A study of Rattus norvegicus with 9 samples.

How the data were processed

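Gene expression was measured in cultured cells of adult Sprague Dawley rats with Affymetrix whole-transcript arrays for the rat (Rat Gene 1.0 ST). The 9 arrays fall into 3 groups of 3 independent samples each. The groups are Schwann cells of the sciatic nerve, Schwann cells made from skin-derived precursors (SKPs) of the dorsal trunk, and the SKPs themselves. SKPs are sphere-forming cells grown from skin. Per the labels' protocols, SKP spheres were collected after passaging, while both kinds of Schwann cell were passaged, grown to confluence in Schwann cell medium and then collected. RNA was extracted with Trizol and a column kit, per the labels' protocols, and labelled as complementary DNA. The labels give the 3 SKP arrays as a reanalysis of earlier deposited samples, so any batch difference between these and the other 6 arrays cannot be told apart from the group. The tissue field of the labels names dermis for all 9 arrays, and groups were taken from the cell type.

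The values analysed were the log2 expression values deposited by the authors for 29214 features. They were made with RMA in Affymetrix Expression Console, per the submitters' processing notes. RMA corrects the background, normalises between arrays and summarises the probes of a feature. Whether the 9 arrays were normalised together, the versions used and the genome build are not given in the sources used here. All 9 columns of values were used. Per-probe signals and detection calls were not used here, so no gene was called detected or absent, and the number of arrays limits the precision.

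Features were named from the platform annotation, in which 15310 features have 1 gene symbol, 323 have several and 13581 have none. Features with several symbols or none were left out of the main tests. Where a gene had more than 1 feature (526 genes), the feature with the highest mean over all arrays stood for it, which left 14506 genes. Of these, 14480 had an Entrez identifier in a RefSeq gene table of assembly GRCr8, used only for names, and 0 symbols were updated. The 9 values of 319 features equalled those of another feature. No coordinates are given.

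Differences between groups were tested with limma 3.58.1 in R 4.3.3. A linear model of the group means (lmFit) was fitted to all 9 arrays, which share 1 estimate of the spread, and variances were moderated with eBayes. P-values were adjusted with Benjamini-Hochberg over the 14506 genes in each comparison, and a gene was called at an adjusted p under 0.05 with no fold minimum. Every adjusted p given for a gene comes from limma, and from this fit unless another scaling or a left-out array is named beside it. The 3 comparisons are nerve Schwann cells minus SKPs, SKP-derived Schwann cells minus SKPs, and SKP-derived minus nerve Schwann cells.

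Shifts of 35 gene lists with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01. Camera compares the members of a list with all other genes. P-values were adjusted with Benjamini-Hochberg over all 105 list tests. Each list was tested again with the correlation estimated from the residuals, and with fry, which asks whether the members of a list move to the same side on balance and compares them with no other genes. The lists cover Schwann cell identity, myelin, repair Schwann cells, neural crest regulators, dermal mesenchyme, SKPs and dermal papilla, somite and mesoderm regulators, Hox genes in 3 sets, signalling pathways, metabolism, proliferation, stress and immunity. Others hold markers of cell types that a nerve or skin culture could contain. Of 775 list entries, 662 were measured. The number of called members was also counted with p-values adjusted over the list alone.

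The genes named were fixed by rule. They are, per comparison, the 6 genes with the largest rise and the 6 with the largest fall among called genes whose groups did not overlap, up to 4 called members of each list described with the largest absolute change, and 12 fixed genes whatever their values. Of the last, 10 of the 12 fixed genes were measured by a feature naming 1 gene. Groups, tests, lists, named-gene rule and the first set of alternative settings were chosen before the data were examined.

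The alternative settings chosen at that point were centring each array on its median, cyclic loess between arrays, leaving out the genes below the median level, all features instead of 1 per gene, the mean of the features of a gene, a fit of only the 2 groups compared, trended and robust variances, array weights, a replicate block, a 2-fold minimum, a stricter threshold of 0.01, and leaving out each array in turn. Quantile normalisation of the deposited values, calls in the same direction under all 4 scalings (as deposited, median-centred, cyclic loess and quantile), and fits without array 2 of the SKP-derived or of both Schwann cell groups were added after seeing the data.

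Because the 2 Schwann cell groups are compared with the same 3 SKP arrays, unchanged groups were simulated 100 times against shared controls. Every split of the 6 arrays of a comparison into 3 and 3 was fitted (10 splits), and 100 splits of the 9 arrays were used for the overlap. Both counts include the real split.

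The pipeline was tested on simulated data with the means and spread of the 14506 genes, in which 50 genes per size were changed. For SKP-derived minus nerve Schwann cells, it recovered 8% of changes of 0.5 on the log2 scale, 56% of changes of 1, 90% of changes of 2 and 100% of changes of 4, and it called 0.0419% of unchanged genes. For SKP-derived Schwann cells minus SKPs the shares were 6%, 62%, 90% and 96%, with 0.0699% of unchanged genes called. For nerve Schwann cells minus SKPs they were 0%, 54%, 90% and 100%, with 0.035% of unchanged genes called. A planted list was recovered in each comparison. The simulated noise was independent between genes and held no offset between groups. These rates therefore do not cover an offset between arrays or correlation between the genes of a list, as the deposited values may hold. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.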

Results

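Transcript levels were compared between Schwann cells of the rat sciatic nerve, Schwann cells derived from dorsal trunk SKPs, and the SKPs themselves, with 3 independent cultures per group. The series asks whether precursors from skin can give rise to Schwann cells. The comparison of both Schwann cell groups with SKPs gives how far each lay from the SKPs, and the comparison between them gives what differs from nerve cells. The nerve cells were not made from SKPs. Differences from SKPs also hold sphere culture against growth to confluence in Schwann cell medium, and any batch of the SKP arrays.

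Both kinds of Schwann cell lay far from SKPs and nearer to each other. Over the 14506 genes, the mean Euclidean distance between a nerve and a SKP-derived array was 83.3 (72.6 to 91.8 over 9 pairs), against 137 between SKP-derived Schwann cell and SKP arrays and 145 between nerve Schwann cell and SKP arrays. Distances within groups were 33.1 for nerve Schwann cells, 61.2 for SKP-derived Schwann cells and 67.0 for SKPs. The first principal component held 66.0% of the variance and the second 15.5%. The distance from SKP-derived to nerve Schwann cells was 0.609 ± 0.0738 (SD, n = 3) of that to SKPs, and 0.460 after cyclic loess.

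The deposited values were not on a fully shared scale. The median over all features was 6.82 to 6.87 in nerve Schwann cells, 6.33 to 6.44 in SKP-derived Schwann cells and 6.2 to 6.27 in SKPs. As deposited, the median gene differed by -0.45 on the log2 scale between SKP-derived and nerve Schwann cells, by -0.01 between SKP-derived Schwann cells and SKPs, and by 0.46 between nerve Schwann cells and SKPs. After cyclic loess these medians were -0.02, -0.03 and -0.03. The difference between the Schwann cell groups was -0.56 over the dimmest features and -0.19 over the brightest. Log2 differences are given as deposited and are to be read against these medians, with loess values beside those that move.

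**Figure D1:**
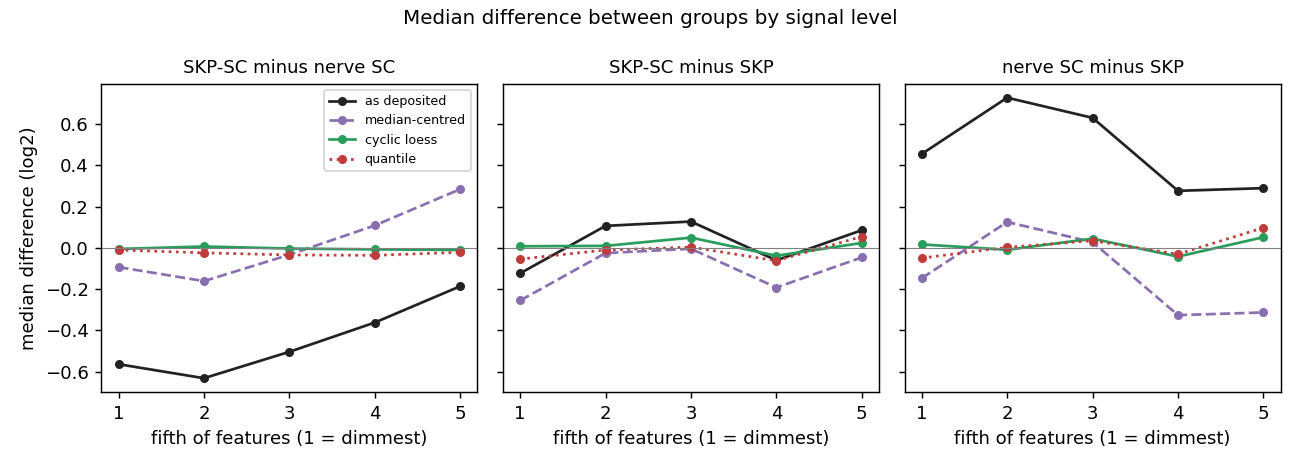
Median log2 difference (y axis) over features ranked by mean level into 5 equal bins (x axis, 1 the dimmest and 5 the brightest), with 1 panel per comparison and 1 line per scaling. As deposited, SKP-derived minus nerve Schwann cells runs from -0.56 in bin 1 to -0.19 in bin 5, and the cyclic loess line stays within 0.01 of 0 in that panel.

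Nerve Schwann cells differed from SKPs by a broad Schwann cell programme that was high in nerve cells, and by dermal mesenchymal and BMP pathway genes that were high in SKPs. Pmp2, a lipid-binding protein of peripheral myelin, had a log2 level of 12.09 ± 0.43 in nerve Schwann cells and 4.12 ± 0.20 in SKPs (SD, n = 3 each), a difference of 7.98 (SE 0.21, limma adjusted p = 6.77e-08). Cdh19, a cadherin of the Schwann cell lineage, differed by 7.60, and Erbb3, the neuregulin receptor subunit of Schwann cells, by 7.48. At the other end, the matrix metalloproteinase Mmp3 fell by 7.33 (6.17 ± 0.26 against 13.50 ± 0.06, SE 0.65, limma adjusted p = 2.96e-05) and Mmp10 fell by 6.13.

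Of the 21 measured members of the Schwann cell identity list, 19 rose and 0 fell (16 and 1 after cyclic loess; 19 and 0 adjusted over the list alone), with a median difference of 4.42. The list was called by camera (limma adjusted p = 3.4e-06, adjusted p = 0.428 with an estimated correlation). The transcription factor Sox10, which specifies the lineage, rose by 4.77, the calcium-binding protein S100b by 4.42, the neurotrophin receptor Ngfr by 5.2 and the adhesion molecule L1cam by 6.43. Itgb4, a laminin receptor subunit, rose by 6.30. The intermediate filament genes Gfap and Nes rose by 3.84 and 3.91, and Sox2, a transcription factor of immature Schwann cells, by 2.01. Outside the lists, the ectonucleotidase Entpd2 rose by 7.09, Plekhb1 by 6.58 and the adhesion molecule Igsf11 by 6.55.

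Of the 19 myelin genes, 16 rose and 0 fell (14 and 0 after cyclic loess; 16 and 0 adjusted over the list alone; limma adjusted p = 0.000375, adjusted p = 0.656 with an estimated correlation). Ugt8, which makes the myelin lipid galactosylceramide, rose by 6.09, the tight junction gene Cldn11 by 5.90 and the myelin protein gene Mbp by 5.83. A second Mbp feature differed by 1.39, so the size of the Mbp change depends on the feature. Lipid synthesis genes Fa2h, a fatty acid hydroxylase of myelin lipids, Elovl6, an elongase, and Aspa rose by 4.90, 4.01 and 3.35. Of the 20 fatty acid genes 10 rose and 2 fell (10 and 2 adjusted over the list alone), and the list was called after cyclic loess but not as deposited (limma adjusted p = 0.0305, against 0.428 as deposited and 0.0989 after median centring; after cyclic loess, adjusted p = 0.815 with an estimated correlation). The list of basal lamina and matrix receptor genes was not called as deposited either (limma adjusted p = 0.333). It was called after cyclic loess (0.0372, where adjusted p = 0.815 with an estimated correlation) and also after median centring (0.0469). Of these genes 12 of 17 rose and 2 fell as deposited (7 and 3 after cyclic loess, and 12 and 3 adjusted over the list alone). Their largest changes were Itgb4, Itgb8 (4.60), Itga7 (3.41) and Dmd, the dystrophin gene (2.63).

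Dermal mesenchymal genes were lower in nerve Schwann cells, with 16 of 25 falling and 2 rising (16 and 0 after cyclic loess; 16 and 2 adjusted over the list alone; limma adjusted p = 9.84e-08, adjusted p = 0.53 with an estimated correlation). Thy1, a fibroblast surface protein, fell by 4.30, the homeobox gene Prrx1 fell by 3.64, the growth factor receptor Pdgfra fell by 3.61 and the matrix gene Fbln1 fell by 3.31. Col1a1, which encodes a collagen I chain, differed by -0.77 and was not called (limma adjusted p = 0.0692), but by -1.17 without SKP array 3, where it was called (0.00315). The SKP arrays were unequal on this list: its mean after cyclic loess was 10.90, 10.82 and 9.38 in SKP arrays 1 to 3. Somite and mesoderm regulators included Twist1, which fell by 2.81, Prrx2, which fell by 2.80, and Tbx15, which fell by 2.02. Of that list 4 rose and 6 fell of 15 (1 and 8 after cyclic loess; 4 and 6 adjusted over the list alone; limma adjusted p = 0.0542 as deposited and 0.0309 after cyclic loess, where adjusted p = 0.815 with an estimated correlation). The Tbx15 call was lost without nerve Schwann cell array 1 (adjusted p = 0.0517) or 3 (0.0523).

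BMP and TGF-beta pathway genes were lower in nerve Schwann cells at 13 of 26 members and higher at 4 (14 and 1 after cyclic loess; 13 lower and 4 higher adjusted over the list alone; limma adjusted p = 1.77e-05, adjusted p = 0.399 with an estimated correlation). Grem1, a secreted BMP antagonist, fell by 4.75, the ligand Bmp2 fell by 4.66, Ltbp2 fell by 3.96 and Smad7, an inhibitor of the pathway, fell by 2.55. SKP and dermal papilla genes were called lower too (10 of 23 fell and 5 rose; 11 and 5 adjusted over the list alone; limma adjusted p = 0.000842, adjusted p = 0.6 with an estimated correlation), but not after cyclic loess (0.0677) or median centring (0.128). In that list Prdm1 fell by 4.31 and Crabp1, a retinoic acid binding protein, fell by 4.04, while Sostdc1, a secreted BMP and Wnt antagonist, rose by 6.19. The other genes with the largest falls were Ccn3 (-5.80), the water channel Aqp1 (-5.63), the secreted phosphoprotein Spp1 (-5.46) and the thyroid hormone deiodinase Dio2 (-5.24).

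Hypoxia and glycolysis, ribosomal protein, antigen presentation and stress lists were also called lower. Of 33 hypoxia and glycolysis genes 15 fell and 4 rose (limma adjusted p = 5.18e-06, adjusted p = 0.656 with an estimated correlation; 15 and 4 adjusted over the list alone), with hexokinase Hk2 at -3.49, Pgk1 at -2.77, Pkm at -2.38 and, on the higher side, Pfkfb4 at 2.21. SKP array 3 stood apart on this list, with a mean of 10.51 after cyclic loess against 9.70 and 9.69 in SKP arrays 1 and 2. Of 30 ribosomal protein genes 17 fell and 3 rose (limma adjusted p = 3.85e-07, adjusted p = 0.684 with an estimated correlation; 17 and 3 adjusted over the list alone). Rps3 fell by 3.39 on the feature used and by 1.71 on another, Rps27 fell by 2.56 and Rpl8 fell by 1.90. Rpl13 fell by 2.33, but 1 of its 7 features differed by 4.60 in the opposite direction. Antigen presentation genes were lower at 5 of 15 and higher at 3 (limma adjusted p = 0.0179, adjusted p = 0.656 with an estimated correlation; 5 and 3 adjusted over the list alone), a call that ended after median centring (adjusted p = 0.104) and without SKP array 1 (0.0505). The list mean after cyclic loess was 7.92, 7.77 and 7.17 in SKP arrays 1 to 3, and that of the macrophage and immune marker list was 7.83, 6.18 and 5.77, so array 1 was highest on both. Psmb8 and Psmb9, subunits of the immunoproteasome, fell by 1.83 and 1.77, and the peptide transporter genes Tap2 and Tap1 fell by 1.82 and 1.72. Stress genes were called lower as deposited (7 of 19 fell and 4 rose; 7 and 4 adjusted over the list alone; limma adjusted p = 0.00264, adjusted p = 0.428 with an estimated correlation) and not after cyclic loess (0.144) or median centring (0.128). Gadd45a and Cdkn1a, both growth-arrest genes, differed by -3.29 and -2.50, whereas the early response genes Atf3 and Fos rose by 4.13 and 3.12.

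The cell cycle list was called lower in nerve Schwann cells than in SKPs (limma adjusted p = 0.000489, adjusted p = 0.77 with an estimated correlation), with 5 of 30 genes lower and 0 higher, and 0 and 0 when limma's p-values were adjusted over the list alone. Ccnd1, a G1 cyclin, fell by 1.04 and the mitotic kinase gene Aurkb fell by 1.11. The calls of Tyms (-1.29) and Cdc6 (-1.06) each ended without single arrays: Tyms without nerve Schwann cell array 1 or 3 or SKP array 1 or 2 (adjusted p up to 0.084), and Cdc6 without nerve array 2 or 3, SKP-derived Schwann cell array 1, or SKP array 1 or 2 (adjusted p up to 0.134). SKP array 3 stood apart on this list, with a mean of 6.75 after cyclic loess against 8.65 and 8.25 in SKP arrays 1 and 2.

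In all, 7211 genes were higher and 2158 lower in nerve Schwann cells than in SKPs, 77.0% of calls being higher. That share was 46.6% after cyclic loess (3244 higher and 3716 lower), 46.3% after quantile normalisation and 35.0% after median centring. Under all 4 scalings 2224 genes were higher and 2155 lower.

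SKP-derived Schwann cells had far higher Schwann cell and myelin transcripts than the SKPs, and lower mesenchymal, BMP pathway and glycolysis transcripts. Pmp2 reached 12.96 ± 0.07 against 4.12 ± 0.20 in SKPs (SD, n = 3 each), a difference of 8.85 (SE 0.21, limma adjusted p = 4.24e-08), Cdh19 rose by 7.02 and Erbb3 by 6.63. The largest falls were Spp1 (13.23 ± 0.56 in SKPs, 6.44 ± 0.45 in SKP-derived Schwann cells, -6.79, SE 0.34, limma adjusted p = 2.26e-06), Mmp10 (-6.52), Aqp1 (-5.97), Dio2 (-5.90), Ccn3 (-5.63) and Ptgs1 (-5.53), a prostaglandin synthase. The median gene differed by -0.01 as deposited.

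Of the 21 Schwann cell identity genes, 18 rose and 0 fell (17 and 1 after cyclic loess; 18 and 1 adjusted over the list alone; median 3.96; limma adjusted p = 3.51e-11, adjusted p = 0.399 with an estimated correlation). The sodium channel gene Scn7a rose by 5.31, Gpr37l1 by 5.15, S100b by 5.10, Ngfr by 4.24 and Sox10 by 3.96. Nes rose by 3.15 and Entpd2 by 6.27. Sox2 differed by 0.80 and was not called (limma adjusted p = 0.235), but by 1.43 without SKP-derived array 2, where it was called (0.0118). Gfap rose by 0.99 (limma adjusted p = 0.0258), a call that ended without SKP-derived Schwann cell array 1 (difference 0.70, adjusted p = 0.0886) or 2 (adjusted p = 0.0513), or SKP array 1 (adjusted p = 0.0883).

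Of the 19 myelin genes 18 rose and 0 fell (18 and 0 after cyclic loess and adjusted over the list alone; median 3.69; limma adjusted p = 1.89e-11, adjusted p = 0.399 with an estimated correlation). Ugt8 rose by 6.52, the tight junction gene Cldn19 by 6.46 and Mbp by 5.85, with the second Mbp feature at 1.04. Fatty acid and lipid synthesis genes rose at 9 of 20 and fell at 3 (10 and 3 adjusted over the list alone; limma adjusted p = 0.00784, adjusted p = 0.441 with an estimated correlation), with Fa2h at 5.09, Elovl6 at 4.01 and the desaturase Fads2 at 3.51.

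**Figure D2:**
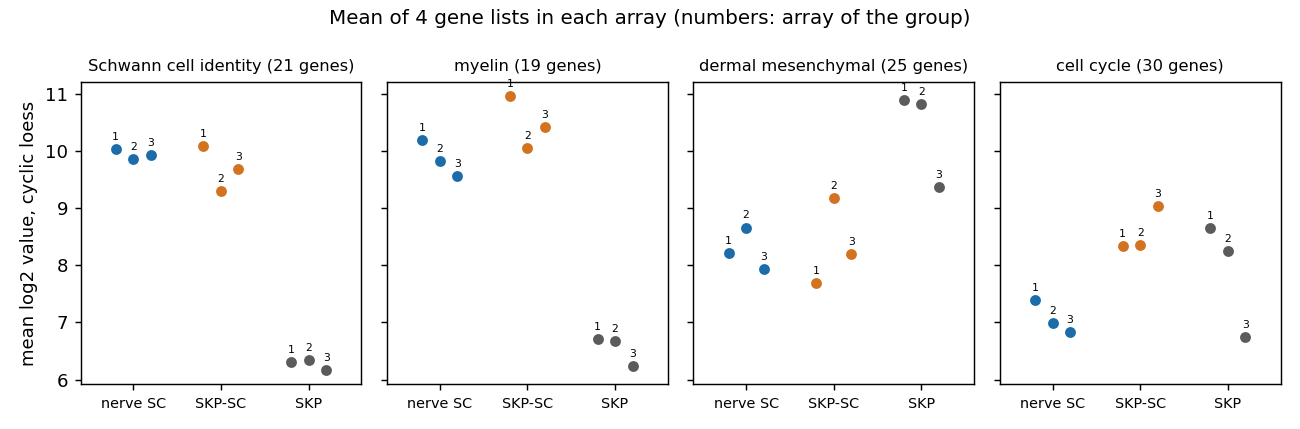
Mean log2 level after cyclic loess (y axis) of the Schwann cell identity (21 genes), myelin (19), dermal mesenchymal (25) and cell cycle (30) lists, with 1 point per array and the 3 groups on the x axis. Identity and myelin means are 9.31 or higher in all 6 Schwann cell arrays and 6.72 or lower in the 3 SKP arrays, and SKP-derived Schwann cell array 2 has the highest dermal mesenchymal mean of its group (9.19).

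Mesenchymal genes fell as the Schwann cell genes rose: 16 of 25 dermal mesenchymal genes were lower and 0 higher (15 and 0 after cyclic loess; 16 and 0 adjusted over the list alone; limma adjusted p = 0.000117, adjusted p = 0.656 with an estimated correlation). Pdgfra fell by 4.23, Prrx1 fell by 3.79, the fibrillin gene Fbn1 fell by 3.67, Fbln1 fell by 3.36 and Col1a1 fell by 1.53. The list mean after cyclic loess was 9.19 in SKP-derived Schwann cell array 2, against 7.70 and 8.19 in arrays 1 and 3. Of 15 somite and mesoderm regulators, 9 fell and 0 rose (9 and 0 adjusted over the list alone; limma adjusted p = 0.00813, adjusted p = 0.656 with an estimated correlation), with Twist1 at -2.73, Prrx2 at -2.36 and Twist2 at -2.12.

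BMP and TGF-beta genes were lower at 16 of 26 and higher at 2 (16 and 2 adjusted over the list alone; limma adjusted p = 0.000608, adjusted p = 0.428 with an estimated correlation). Bmp2 fell by 5.13, Grem1 fell by 4.72, Ltbp2 fell by 4.15 and Inhba, which encodes an activin subunit, fell by 3.35. SKP and dermal papilla genes moved both ways and were not called as a list (13 of 23 lower and 3 higher; 14 and 4 adjusted over the list alone; limma adjusted p = 0.108), with Prdm1 at -4.18, the ligand gene Wnt5a at -3.71 and Sostdc1 at 5.53.

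Hypoxia and glycolysis genes fell at 16 of 33 and rose at 2 (16 and 2 adjusted over the list alone; limma adjusted p = 0.000426, adjusted p = 0.684 with an estimated correlation), including Hk2 (-3.90), the collagen prolyl hydroxylase subunit P4ha2 (-3.08), Pgk1 (-2.74) and Pkm (-2.60). The SKP level of this list was raised by array 3 (mean of 10.51 after cyclic loess, against 9.70 and 9.69 in arrays 1 and 2). Antigen presentation genes fell at 6 of 15 and rose at 0 (6 and 0 adjusted over the list alone; limma adjusted p = 0.0139, adjusted p = 0.656 with an estimated correlation), among them Tap1 (-2.52), Psmb8 (-2.45), Tap2 (-2.12) and Tapbp (-1.56). SKP array 1, which had the highest mean of this list (7.92 after cyclic loess), also had the highest mean of macrophage and immune markers (7.83, against 6.18 and 5.77 in SKP arrays 2 and 3). Ribosomal protein genes were lower at 13 of 30 and higher at 6 (15 and 6 adjusted over the list alone), and the list was called after cyclic loess but not as deposited (limma adjusted p = 0.0464, against 0.159 as deposited and 0.231 after median centring; after cyclic loess, adjusted p = 0.933 with an estimated correlation). Rps3 fell by 3.03, with its other feature at -1.47, Rps27 fell by 2.40 and Rpl8 fell by 1.52. Rpl13 fell by 1.99, again with 1 of its 7 features in the opposite direction (4.29).

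The cell cycle list was not called (8 of 30 higher and 1 lower, also adjusted over the list alone; limma adjusted p = 0.0776, and 0.076 after cyclic loess). After median centring it was called higher (0.0261), while adjusted p = 0.884 with an estimated correlation as deposited. Nusap1 and Ccna2, genes of the spindle and of S and G2 phase, rose by 2.48 and 2.41. The Bub1 call (1.98) ended without SKP-derived Schwann cell array 3 (adjusted p = 0.0778), and that of Cdk1 (1.26) after median centring (adjusted p = 0.0515) and without SKP-derived array 1 or 3 or SKP array 2 or 3 (adjusted p up to 0.115). Without SKP array 3 the differences were smaller: 1.64 for Nusap1, 1.21 for Bub1 and 0.79 for Cdk1. SKP array 3 had the lowest cell cycle mean of all arrays, 6.75 after cyclic loess.

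**Figure D3:**
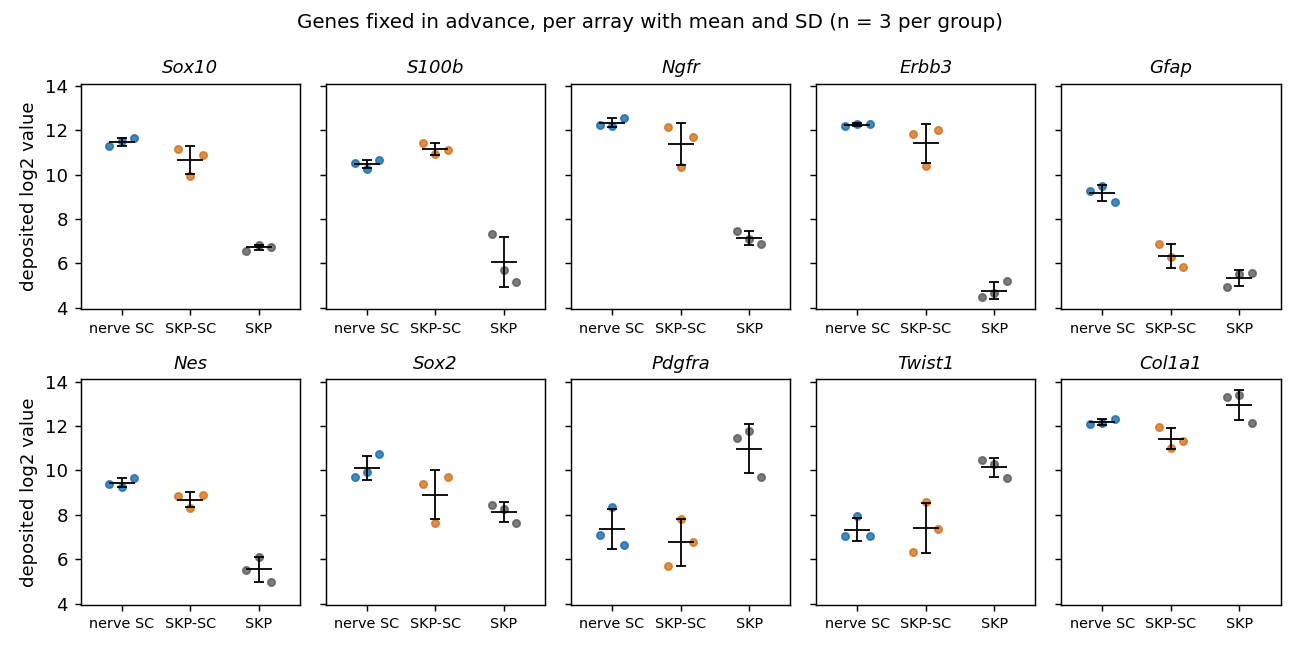
Deposited log2 level (y axis) of the 10 measured fixed genes, 1 panel each, in the 3 groups (x axis), with dots for arrays and a line and bar for the mean ± SD (n = 3). Sox10, S100b, Ngfr, Erbb3 and Nes are high in both Schwann cell groups and low in SKPs, while Gfap averages 9.18 in nerve Schwann cells, 6.32 in SKP-derived Schwann cells and 5.34 in SKPs.

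Counting all genes, 2806 were higher and 3232 lower in SKP-derived Schwann cells than in SKPs, 46.5% of calls being higher. The share was 43.9% after cyclic loess and 34.7% after median centring. Under all 4 scalings 2075 genes were higher and 3099 lower.

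Many genes were called in the same direction against SKPs in both Schwann cell groups. There were 2639 genes higher in both and 1964 lower in both, 4603 in all, while 68 were called in opposite directions. Independent lists of these lengths would share 1395, 481 and 2024 genes. Unchanged groups simulated against shared controls gave a mean of 0.01 genes higher in both and 0 lower in both with limma's adjusted p-values. These simulated groups held no differences, so counts near 0 had to follow and do not test the overlap. Groups with unrelated real changes, or a batch of the SKP arrays, were not simulated. Across genes, which are not independent replicates, the log2 differences had a covariance of 1.04 against 0.0367 in the simulation (r = 0.913 against 0.5). After cyclic loess the counts were 2124, 2902 and 6, against 605, 887 and 1467 for independent lists. Part of the excess may come from the shared SKP arrays, and 3 arrays cannot be split into sets of 2.

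**Figure D4:**
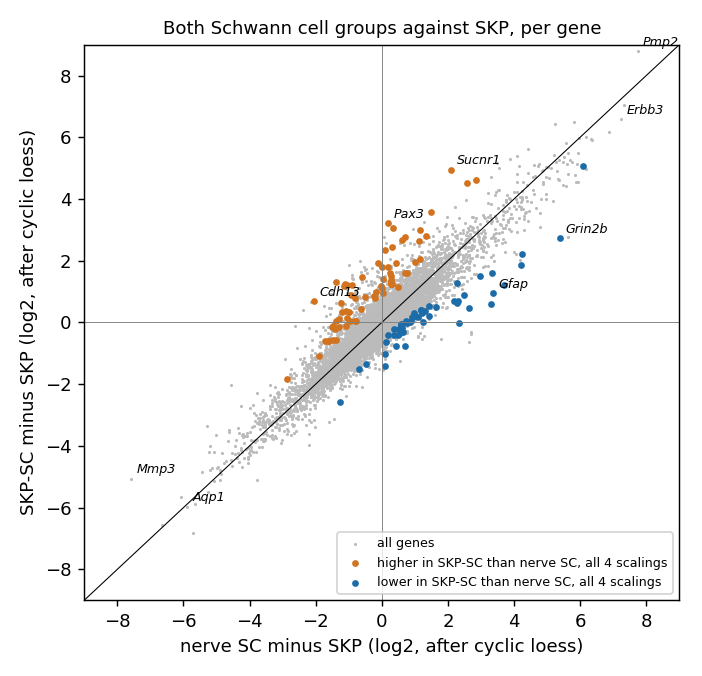
Each point is a gene, with its log2 difference after cyclic loess in nerve Schwann cells minus SKPs on the x axis and in SKP-derived Schwann cells minus SKPs on the y axis. Coloured points are the 69 genes higher and 51 lower in SKP-derived than in nerve Schwann cells under all 4 scalings, and the other genes follow the diagonal (r = 0.925 over all genes).

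Against nerve Schwann cells, the cell cycle and myelin lists were called higher in SKP-derived Schwann cells relative to other genes, and Gfap was lower. Both list calls were lost with an estimated correlation (adjusted p = 0.428 for cell cycle and 0.399 for myelin as deposited, 0.815 for both after cyclic loess), and limma called 0 single myelin genes after cyclic loess. As deposited, the estimated correlation left 0 of 35 lists called in each comparison, so that loss does not set these 2 lists apart. The neural crest transcription factor gene Pax3 was at 9.04 ± 0.55 in SKP-derived and 6.45 ± 0.30 in nerve Schwann cells (SD, n = 3 each), a difference of 2.58 as deposited (SE 0.28, limma adjusted p = 0.00192) and 3.01 after cyclic loess. Gfap was at 6.32 ± 0.53 and 9.18 ± 0.37, a difference of -2.86 (SE 0.30, limma adjusted p = 0.00192) and -2.41 after cyclic loess. Several core lineage genes were not called: S100b differed by 0.68 (limma adjusted p = 0.239), Erbb3 by -0.85 (0.0903), Ngfr by -0.96 (0.073), Sox2 by -1.21 (0.0768) and Nes by -0.76 (0.0501). Without SKP-derived array 2 the differences were -0.35 for Erbb3, -0.44 for Ngfr and -0.58 for Sox2. Mesenchymal genes Col1a1 (-0.76, limma adjusted p = 0.0926), Pdgfra (-0.62, 0.471) and Twist1 (0.08, 0.904) were not called either. The Pdgfra difference ran from -1.14 without SKP-derived array 2 to -0.09 without SKP-derived array 1.

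How many genes differed rested on the scaling. As deposited, 193 genes were higher and 6140 lower (3.05% of calls higher). Cyclic loess gave 106 higher and 87 lower (54.9%; 2908 genes at an unadjusted p under 0.05), quantile normalisation 130 and 110 (54.2%), and median centring 482 and 234 (67.3%). Under all 4 scalings 69 genes were higher and 51 lower, of which 33 and 22 differed by 2-fold or more both as deposited and after cyclic loess. The count as deposited fell to 3982, 3755 and 4005 without nerve Schwann cell array 1, 2 or 3.

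The genes with the largest rises were the cadherin Cdh13 (2.59 as deposited, 2.75 after cyclic loess), Pax3, Rrm2 (2.56, 2.83), the succinate receptor gene Sucnr1 (2.44, 2.84), Cdkn3 (2.42, 2.84) and the complement regulator Cd55 (2.38, 2.68). Of these Cdh13, Pax3 and Sucnr1 were called under all 4 scalings and without each array in turn. The largest falls were Apod, which encodes a lipocalin (-3.45, -3.29), Abcg3l3 (-3.38, -3.08), the endopeptidase Ecel1 (-3.25, -2.71), Sparcl1 (-3.19, -3.02), Cldn11 (-3.13, -2.86) and the glutamate receptor subunit Grin2b (-3.09, -2.65), of which Ecel1 and Grin2b were called under all 4 scalings and without each array. Single arrays ended the calls of Rrm2 (nerve array 2 or 3, SKP-derived array 1 or 3; adjusted p up to 0.0905), Cdkn3 (nerve array 2 or 3, SKP-derived array 3; up to 0.0603) and Cldn11 (nerve array 1 or 2, SKP-derived array 2; up to 0.065). Without SKP-derived array 3 the Cldn11 difference was -2.05.

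The cell cycle list was called higher in SKP-derived Schwann cells (limma adjusted p = 3.1e-28 as deposited, 6.46e-14 after cyclic loess, adjusted p = 0.428 with an estimated correlation). Its median difference was 1.08 as deposited and 1.49 after cyclic loess. Of 30 genes 12 rose and 0 fell as deposited (12 and 0 adjusted over the list alone), and 3 and 0 after cyclic loess (25 and 0 adjusted over the list alone). The spindle checkpoint kinase gene Bub1 rose by 2.28, a call lost after cyclic loess (2.66, limma adjusted p = 0.0642), and Cdk1, the mitotic kinase gene, by 1.93 (2.36 after cyclic loess, limma adjusted p = 0.0384). Tpx2, a spindle gene, rose by 1.91, a call that ended after cyclic loess (2.25, limma adjusted p = 0.129) and without any 1 of the 6 Schwann cell arrays (adjusted p up to 0.122). The list mean after cyclic loess was 8.33, 8.36 and 9.04 in SKP-derived Schwann cell arrays 1 to 3, and 7.40, 6.99 and 6.84 in nerve Schwann cell arrays 1 to 3.

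The myelin list was called higher than other genes (limma adjusted p = 8.89e-11 as deposited, 0.000569 after cyclic loess, adjusted p = 0.399 with an estimated correlation), with a median difference of 0.43 as deposited and 0.76 after cyclic loess. The groups overlapped on this list: its mean after cyclic loess was 10.19, 9.82 and 9.56 in nerve Schwann cell arrays 1 to 3 and 10.96, 10.05 and 10.42 in SKP-derived Schwann cell arrays 1 to 3. Of 19 genes 4 rose and 1 fell (4 and 1 adjusted over the list alone), and limma called 0 and 0 after cyclic loess (7 and 1 adjusted over the list alone). Gldn, which organises nodes of Ranvier, rose by 1.66, the myelin glycoprotein gene Mag by 1.15 and the periaxin gene Prx by 1.14. After cyclic loess the differences were larger, 1.81 (SE 0.56), 1.47 (SE 0.39) and 1.40 (SE 0.32), but were not called (limma adjusted p = 0.127, 0.0929 and 0.069). The calls also ended without single arrays: Gldn without any nerve array or SKP-derived array 1 or 2 (up to 0.0806), Mag without nerve array 2 or 3 or any SKP-derived array (up to 0.098, with a difference of 0.73 without nerve array 3), and Prx without nerve array 2 or 3 or SKP-derived array 1 or 3 (up to 0.0839).

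The Schwann cell identity list was not called (1 of 21 higher and 9 lower, also adjusted over the list alone, 1 and 1 after cyclic loess; limma adjusted p = 0.699, and 0.0872 after cyclic loess). After quantile normalisation it was called lower (0.0284), while adjusted p = 0.917 as deposited and 0.819 after cyclic loess with an estimated correlation. SKP-derived array 2 was low on this list, with a mean of 9.31 after cyclic loess against 10.09 and 9.69 in arrays 1 and 3. L1cam fell by 1.45 (-1.19 after cyclic loess, limma adjusted p = 0.0505), Foxd3, a neural crest transcription factor gene, fell by 1.21 and Sox10 fell by 0.81 (limma adjusted p = 0.0379). The Foxd3 and Sox10 calls were lost after cyclic loess (-0.90 and -0.62, limma adjusted p = 0.157 and 0.214). They also ended without any nerve array, and that of Sox10 without SKP-derived array 2 or SKP array 2 (adjusted p up to 0.111). Without SKP-derived array 2 the differences shrank to -0.46 for Sox10 and -0.77 for Foxd3.

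Further lists were called higher relative to other genes. Ribosomal protein genes had a median of 0.24 (0.33 after cyclic loess; limma adjusted p = 1.65e-17, adjusted p = 0.441 with an estimated correlation), with 2 of 30 higher and 0 lower, and limma gave 0 and 0 adjusted over the list alone. Rps7 rose by 1.13 and Rps4x by 0.44. Cholesterol synthesis genes had a median of 0.14 (limma adjusted p = 1e-06, adjusted p = 0.656 with an estimated correlation; 1 of 20 higher and 1 lower, 0 and 0 adjusted over the list alone), with Hsd17b7 at 0.79 and Mvd at -0.43 (-0.07 after cyclic loess, 0.04 after median centring). Stress genes had a median of -0.001 and a mean of 0.13 (limma adjusted p = 2.3e-07, adjusted p = 0.399 with an estimated correlation; 2 of 19 higher and 0 lower, 1 and 0 adjusted over the list alone), with the immediate early genes Ier2 at 1.01 and Ier3 at 0.96. Of these genes Ier2 was called under all 4 scalings and without each array. The calls of Rps7, Rps4x, Hsd17b7, Mvd and Ier3 each ended without 4 or more of the single arrays and after cyclic loess. The differences after cyclic loess were 1.22 for Rps7, 0.33 for Rps4x, 1.13 for Hsd17b7, -0.07 for Mvd and 1.15 for Ier3, so that only Mvd came near 0. Without SKP-derived array 2 the Ier3 difference was 0.62. The arrays were nerve arrays 1 and 2 for all of them, nerve array 3 for Rps4x, Hsd17b7 and Mvd, SKP-derived array 1 for Mvd and Ier3, array 2 for all of them, array 3 for all but Ier3, and SKP arrays 1 and 2 for Ier3 (adjusted p up to 0.167).

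Other list calls were lost after cyclic loess. Fatty acid synthesis (median -0.03; limma adjusted p = 0.000489, adjusted p = 0.399 with an estimated correlation; 0 of 20 higher and 1 lower, 0 and 0 adjusted over the list alone), ERBB and MAPK feedback (-0.19; 0.0104, adjusted p = 0.492 with an estimated correlation; 2 higher and 5 lower of 23, 1 and 4 adjusted over the list alone), dermal mesenchyme (-0.31; 0.0104, adjusted p = 0.725 with an estimated correlation; 0 and 2 of 25, 0 and 2 adjusted over the list alone) and SKP and dermal papilla genes (-0.39; 0.0112, adjusted p = 0.656 with an estimated correlation; 0 and 2 of 23, 0 and 1 adjusted over the list alone) had negative medians yet were called higher relative to a median gene at -0.45. After cyclic loess none of these was called (0.53, 0.737, 0.869 and 0.647), and after median centring only the fatty acid list was (0.0199, against 0.322, 0.926 and 0.66 for the others). The dermal mesenchymal call also ended without nerve array 3 (0.0686), SKP-derived array 2 (0.268) or SKP array 3 (0.0616), the ERBB and MAPK call without SKP-derived array 2 (0.101), and the SKP and dermal papilla call without nerve array 3 (0.0732) or SKP-derived array 2 (0.163). Array 2 had the highest dermal mesenchymal mean of the SKP-derived Schwann cells, 9.19 after cyclic loess.

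Among the members of these lists, Hey1, a Notch target, fell by 2.12 (-1.74 after cyclic loess) and was called under all 4 scalings and without each array. The MAPK-responsive genes Etv1, Fosl1 and Spry2 fell by 1.47, 1.23 and 0.95 as deposited, with loess values of -1.27, -0.92 and -0.64. Of these loess values that of Spry2 was called (limma adjusted p = 0.0273), but the Spry2 call was lost under 1 other scaling. Under all 4 scalings 1 gene of the ERBB and MAPK feedback list was higher and 0 were lower. Dusp6, a MAPK feedback gene named after its value was seen, rose by 0.92 (1.01 after cyclic loess) and was called under all 4 scalings. Col1a2 fell by 0.91 (-0.92 after cyclic loess, limma adjusted p = 0.0988) and the lipid enzyme gene Acly fell by 0.89 (-0.82, 0.144), a call that also ended without any nerve array (up to 0.0722), with a difference of -0.58 without SKP-derived array 2. Bmp4 and Dpp4 fell by 0.78 and 0.64 as deposited and differed by -0.11 and -0.01 after cyclic loess. The Bmp4 call ended without any nerve array or SKP-derived array 1 or 3 (up to 0.101).

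With an estimated correlation, camera called 0 of the 35 lists in each comparison, and 5, 3 and 3 lists had an unadjusted p under 0.05 in SKP-derived minus nerve Schwann cells, SKP-derived Schwann cells minus SKPs and nerve Schwann cells minus SKPs. The smallest camera adjusted p was 0.399. The myelin list in SKP-derived Schwann cells minus SKPs was not called either, although nearly all of its genes rose. Losing a call in this way therefore does not set a list apart from the others. The fry test, which compares a list with no other genes, called 23, 18 and 24 lists. Between the Schwann cell groups all 23 were lower and 0 of the 9 camera calls, all higher, were shared. Against SKPs fry called 7 higher and 11 lower for SKP-derived Schwann cells and 18 higher and 6 lower for nerve Schwann cells. Fry was run on the deposited values only. There the median gene differed by -0.45 between SKP-derived and nerve Schwann cells and by 0.46 between nerve Schwann cells and SKPs. An offset of that kind enters the fry counts, so their directions cannot be read as changes of the lists alone.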

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

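The tests of the offset between arrays, of a real fall in most genes, of scaling as the source of the mesenchymal and cell cycle patterns, and of array 2 against the level of SKPs were chosen only after the results were seen. The features counted in the next paragraph under all 4 scalings also use quantile normalisation, which was added after seeing the data.

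Features without a single gene name, which the comparisons above leave out, also differed between Schwann cells and SKPs. Of 13904 such features, 1262 (9.08%) were higher by 2-fold or more in SKP-derived Schwann cells than in SKPs under all 4 scalings, and 1141 (8.21%) were higher in nerve Schwann cells than in SKPs. Among features with 1 gene name the shares were 7.38% and 5.88%. Lower by 2-fold or more were 765 (5.5%) and 466 (3.35%) of the unnamed features, against 11.2% and 8.02% of features with 1 gene name, so the difference in shares ran the opposite way. Between the Schwann cell groups 33 unnamed features (0.237%) were higher and 24 (0.173%) lower in SKP-derived cells, against 0.261% and 0.144% of features with 1 gene name.

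In SKP-derived against nerve Schwann cells, 6140 of the 6333 genes called on the deposited values were lower. The median difference over the dimmest features minus that over the brightest was -0.378, which is consistent with an offset between arrays that depends on intensity. From the dimmest to the brightest of the 5 bins the medians were -0.564, -0.632, -0.504, -0.362 and -0.186, so the measured fall was not of similar size at all levels. A real fall of similar size beneath such an offset stays open. The brightest features, with a median difference of -0.186, lay between the bounds set for and against it. A difference in total RNA per cell was not measured.

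Array 2 of the SKP-derived Schwann cells had higher mesenchymal genes than arrays 1 and 3, with 16 of the 25 list genes over 1 higher on the log2 scale after cyclic loess. Among them were Lum (3.6), Prrx1 (3.41), Thy1 (2.89) and Dpt (2.89), whereas Col1a1 (-0.59) and Col5a2 (-0.74) were lower. In the same array the median deviation was -0.53 for Schwann cell identity genes, -0.63 for myelin genes and 0.52 for SKP and dermal papilla genes. The tables argue against scaling as the source, because the median deviation of the list was 1.40 as deposited and 1.55 after cyclic loess. Carry-over of SKPs in that culture stays open: 543 SKP-specific genes outside the list implied a share of 5.81% SKP RNA and 13 list genes 23.3%, a ratio of 0.249 with bootstrap bounds of 0.169 and 0.876. Carry-over with SKP levels unchanged cannot by itself lift a gene above those levels. Of 448 genes over 1 higher in array 2 after cyclic loess, 175 lay above every SKP array, 101 of them by over 1. Examples, named after their values were seen, were Ogn (11.05 in array 2 and a mean of 6.16 in SKPs, as deposited), Frzb (10.27 and 5.91) and Cldn1 (9.96 and 6.13). The 448 were picked by high values in array 2, which favours such a result. SKPs carried over into Schwann cell medium may not keep the levels of spheres, which was not tested. Carry-over is therefore not excluded for these genes. Of the 16 list genes, 4 lay above the SKP mean after cyclic loess (5 as deposited) and 2 above every SKP array. Skin or nerve fibroblasts could also be a source and were tested only by marker medians in that array, 0.42 for endoneurial fibroblasts and 0.13 for perineurial cells. Nerve Schwann cell array 2 was likewise highest of its group on the mesenchymal list, although these cells were not made from SKPs. Its mean after cyclic loess was 8.66, against 8.21 and 7.94 in nerve arrays 1 and 3. Its endoneurial fibroblast mean was 8.04, against 7.45 and 7.06.

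Cell cycle genes were higher in SKP-derived than in nerve Schwann cells. Scaling between arrays is argued against as the whole source, because the lowest list median over the 4 scalings was 1.08. A single array is argued against as well, since the list was called without each of the 6 arrays in turn, with a highest adjusted p of 1.95e-21, and the lowest list median without 1 array was 1.25 after cyclic loess. The list call itself, like every list call on the deposited values, was lost with an estimated correlation (adjusted p = 0.428 as deposited, 0.815 after cyclic loess). Other splits of the arrays called as many lists. Origin of the cells, growth rate and confluence at collection stay open and were not tested.

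For the 3 against 3 comparisons there are 10 splits of the 6 arrays, so the share of splits as large as the real one is never under 0.1. The real split called 6333 genes in SKP-derived against nerve Schwann cells, 6038 in SKP-derived Schwann cells against SKPs and 9369 in nerve Schwann cells against SKPs. It was 1 of the 10 splits with as many in each case, and the highest other split gave 0 with limma's adjusted p-values. At an unadjusted p under 0.05 the highest other splits gave 371, 1185 and 310 genes, against 7755, 7241 and 9876. For gene lists, 6 of the 10 splits called as many as the real 9 in the first comparison (highest other 12), 7 as many as the real 8 in the second (highest other 14) and 5 as many as the real 10 in the third (highest other 13). For the overlap of calls against SKPs, 1 of 100 splits of the 9 arrays was as large as the real 4603, and it was the real split itself. The share could therefore not lie under 0.01. These splits mix all 9 arrays, so anything that sets the SKP arrays apart, a batch included, could give such an overlap. They do not test agreement beyond the shared SKP arrays. The highest other, 3439, came from a split that kept 1 group of the labels whole.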

How the results depend on the processing

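Quantile normalisation, calls under all 4 scalings and the fits without array 2 were chosen only after the data were seen. The cause of a change was not tested unless a setting uses fewer genes or arrays. Both comparisons with SKPs held better than the comparison of the Schwann cell groups with each other. Of the values of named genes under alternatives, 1007 of 1024 kept their direction and side of the threshold for nerve Schwann cells minus SKPs, 865 of 880 for SKP-derived Schwann cells minus SKPs, and 528 of 704 for SKP-derived minus nerve Schwann cells (159 fell below the threshold, 11 passed it and 6 reversed). Of the summary values 117 stayed near the reported value and 34 moved. Called lists kept their call at 409 values, lost it at 72 and reversed at 5. No detection calls were used, so changes between dim genes, which lie near background, may be compressed. Leaving out genes below the median level left 600 genes in SKP-derived minus nerve Schwann cells and 4203 in nerve Schwann cells minus SKPs, with fewer genes tested. These counts do not show such compression. Between the Schwann cell groups the deposited median difference was larger over the dimmest features (-0.564) than over the brightest (-0.186).

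Genes differing between SKP-derived and nerve Schwann cells numbered 6333 as reported, 716 after median centring, 193 after cyclic loess, 240 after quantile normalisation, 13090 over all features, 807 with a 2-fold minimum, 2818 at an adjusted p under 0.01, 120 under all 4 scalings, 3308 without array 2 of both Schwann cell groups and 66 after cyclic loess without SKP-derived array 2. Leaving out each array gave 3755 to 7270, the lowest without nerve array 2. SKP-derived Schwann cells minus SKPs gave 11640 over all features, 2980 with a 2-fold minimum and 3855 at 0.01, with 4865 to 5939 when each array was left out. Nerve Schwann cells minus SKPs gave 18792 over all features, 4174 with a 2-fold minimum and 4379 under all 4 scalings, with 8016 to 9783 when each array was left out.

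Camera with an estimated correlation called 0 lists in each comparison, with 5, 3 and 3 at an unadjusted p under 0.05, and fry called 23 (all lower, sharing 0 with the 9 reported, all higher), 18 and 24. Of the 9 lists between the Schwann cell groups, cyclic loess and leaving out dim genes each left 5, and of the 8 between SKP-derived Schwann cells and SKPs leaving out dim genes left 5. Each array left out gave 6 to 11, 8 to 11 and 9 to 14 lists. The overlap of 4603 was 2164 with a 2-fold minimum and 3867 to 4599 when each array was left out. The distance ratio of 0.609 was 0.488 after median centring, 0.460 after cyclic loess, 0.462 without dim genes, 0.240 on 1 minus Pearson r, and 0.577 to 0.650 when each array was left out.

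All reversals lay between the Schwann cell groups. The dermal mesenchymal list turned lower with fry (adjusted p = 0.432) and cyclic loess (0.869). With fry, so did the ERBB and MAPK feedback (0.0887), fatty acid synthesis (0.626) and SKP and dermal papilla lists (0.25), a test that is not relative to other genes. Twist1 (0.08) ranged from -0.50 without SKP-derived array 2 to 0.64 without SKP-derived array 1, with -0.07 without nerve array 1 or 3 and -0.20 without array 2 of both groups, and was never called. Mvd (-0.43) was 0.042 after median centring and Dpp4 (-0.64) was 0.014 after quantile normalisation.

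With a replicate block the counts of genes were 6169 between the Schwann cell groups, 5898 for SKP-derived Schwann cells minus SKPs and 9294 for nerve Schwann cells minus SKPs, of lists 9, 9 and 11, and of the overlap 4529, and no count moved by over 1.5 times. The labels state no pairing by replicate number, and correlations over 3 arrays per group cannot show whether there was one. Between the Schwann cell groups, deviations of same-numbered arrays correlated by 0.072, 0.289 and 0.148. They correlated by -0.124, 0.046 and 0.031 for SKP-derived Schwann cells and SKPs, and by 0.038, 0.072 and 0.188 for nerve Schwann cells and SKPs. Not every array correlated best with its own number, but arrays 2 and 3 did between the Schwann cell groups.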

Other observations

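The Hox test below was chosen only after the result was seen, as was the reading of the neural crest test and the use of all 4 scalings to sort genes over the 3 groups.

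Some genes set SKP-derived Schwann cells apart from both other groups. Under all 4 scalings 42 of 14506 genes were higher than in nerve Schwann cells and in SKPs, and 9 were lower than in both. They come from the 69 higher and 51 lower genes of the comparison with nerve Schwann cells. Beside Pax3, the higher genes included the succinate receptor Sucnr1 (log2 levels of 7.31 in nerve Schwann cells, 9.75 in SKP-derived Schwann cells and 4.80 in SKPs), Ddah1, an enzyme of arginine metabolism (10.18, 11.94 and 7.37), the serine synthesis enzyme Psat1 (9.21, 10.80 and 8.95), the growth factor Fgf1 (6.72, 7.65 and 4.76), the transcriptional inhibitor Id2 (10.64, 11.78 and 10.13) and the cyclin Ccnd2 (9.52, 11.51 and 10.20). Lower than in both were the procollagen protease Adamts2 (9.85, 8.09 and 9.50), Stac2 (8.28, 6.64 and 9.24) and Sarm1, an axon degeneration gene (6.24, 4.81 and 5.35). These examples were chosen after their values were seen.

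A graded order was called at few genes, and only the 51 genes lower and 69 higher in SKP-derived than in nerve Schwann cells under all 4 scalings could show one. SKP-derived Schwann cells lay between the other groups, with nerve Schwann cells highest, at 10 genes, among them Grin2b (10.02, 6.93 and 4.18 in nerve, SKP-derived and precursor cells), Baalc (10.32, 7.94 and 5.77), Hey1 (9.54, 7.42 and 5.85) and the growth factor Btc (10.05, 7.20 and 6.04). They lay between with SKPs highest at 6 genes, such as Wee1, a kinase that delays mitosis (6.83, 7.46 and 8.09). SKP-derived Schwann cells and SKPs were both lower than nerve Schwann cells at 41 genes, which include the 10, and both higher at 23 genes, which include the 6.

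The remaining gene lists were not called in any comparison on the deposited values, and the smallest of the 3 limma camera adjusted p-values is given for each. Among lineage and signalling lists it was 0.0542 for basal lamina and matrix receptors, 0.0681 for neural crest regulators, 0.09 for Wnt signalling, 0.171 for repair Schwann cells, 0.204 for neurotrophic factors, 0.218 for cAMP-responsive genes and 0.401 for Notch signalling. It was 0.0958 for interferon response genes, and 0.105, 0.337 and 0.193 for Hox groups 1 to 5, 6 to 9 and 10 to 13. Among markers of other cell types it was 0.168 for skeletal muscle, 0.18 for pericytes and smooth muscle, 0.19 for macrophages, 0.206 for endothelium, 0.341 for keratinocytes, 0.663 for perineurial cells, 0.669 for endoneurial fibroblasts, 0.672 for melanocytes, 0.759 for neurons and 0.795 for adipocytes.

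Because Pax3 led the genes higher in SKP-derived Schwann cells than in both other groups, neural crest regulators were tested for over-representation among the 42. The list holds 18 measured genes, of which 1 (Pax3) was in the set (one-sided Fisher exact p = 0.0509, adjusted p = 0.424 over the 35 lists). The bound written against the hypothesis before the test, a p of 0.05 or more, was met. Since Pax3 prompted the test and was its only gene, the test restates what was seen and decides nothing in either direction, a reading chosen after the value was seen. The cell cycle list had 2 genes in the set, Pcna and Ube2c (one-sided Fisher exact p = 0.00338, adjusted p = 0.118).

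SKPs of the trunk might pass their Hox levels on to the Schwann cells made from them. Of 22 measured Hox genes, 2 (Hoxa5 and Hoxa7) differed between nerve Schwann cells and SKPs under all 4 scalings, both higher in SKPs, with Hoxa5 at 5.94, 5.59 and 7.68 and Hoxa7 at 6.45, 5.87 and 7.13 in nerve, SKP-derived and precursor cells. In SKP-derived Schwann cells both genes were lower than in SKPs under all 4 scalings (highest limma adjusted p = 0.00125) and lay closer to nerve Schwann cells. Their SD over the SKP-derived arrays was 0.84 for Hoxa5 and 0.4 for Hoxa7. Both genes were picked by high values in the same SKP arrays, which favours such a result, as would a batch of these arrays. Whether the lower levels lay near background was not tested. The test therefore cannot decide whether SKP-derived Schwann cells keep the Hox levels of SKPs. Over the 22 genes, 10 differed between SKP-derived Schwann cells and SKPs under all 4 scalings and 0 between the Schwann cell groups, which does not show that those were equal. As deposited, Hox genes were called lower in SKP-derived than in nerve Schwann cells at 6 of 11 (groups 1 to 5), 4 of 6 (6 to 9) and 4 of 5 (10 to 13), on a scale where the median gene differed by -0.45, and at 0 after cyclic loess. The Hox genes not called between nerve Schwann cells and SKPs cannot separate the 2 origins.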
